A study of Mus musculus with 2425 samples.

How the data were processed

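Bone marrow-derived dendritic cells (BMDCs) of the mouse were stimulated, captured singly and sequenced after cDNA amplification, and population controls were prepared in tubes. The values analysed were TPM, each gene's length-scaled share of a library's transcripts on a common total, made by the authors with Bowtie 0.12.7 and RSEM 1.11 on the mm9 genome according to the deposited processing notes. A first deposited table held 27723 genes for 1848 cells and 13 population controls, and a second held 10972 genes for 564 cells. TPM keeps no read totals, so the depth of each library is unknown and the number of genes per cell was used in its place. Gene symbols were used as deposited, and 69.2% of the first table's symbols and 84.0% of the second's were found in the mouse annotation at hand. No genome positions are given, since the annotation at hand is on a later build than mm9.

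Cells were grouped by the condition and replicate in their labels. The unit of replication was the culture (in the second table, the set), because cells of a culture are not independent replicates. The first table held 20 cultures in 18 conditions, with 2 cultures for the unstimulated and the lipopolysaccharide (LPS) 4 h condition and 1 for each other. The second held 10 sets in 8 conditions, with 2 sets for LPS 2 h and for LPS 4 h. The labels call these pairs technical replicates, so p-values from the second table measure technical spread and not the spread between cultures. The tables were never mixed in a test. The column names of the second table's Ifnar1 knockout set carry another time code than the 2 h of its label, and the label was used.

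Cells with at least 2000 genes at a TPM of 1 or more were kept, 1460 in the first table and 521 in the second. Values were taken as log2(TPM + 1) and averaged over the kept cells of each culture. Genes at a TPM of 1 or more in at least 10% of the cells of at least 1 culture were tested, 11537 in the first table and 9809 in the second. All conditions of a table were fitted together in limma 3.58.1 (R 4.3.3) with a trend of the variance on the mean, which left 2 residual degrees of freedom, with 4.84 and 5.46 prior degrees of freedom. A condition with a lone culture was assumed to vary like the replicated conditions. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Differences are on the log2(TPM + 1) scale, which understates ratios of genes near 0, and ± marks their standard error. In every comparison of a lone culture or set, the direction of a gene was seen in 1 of 1 culture against the mean of 2.

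Gene lists were written from textbook knowledge. They covered antiviral interferon-stimulated genes, type I interferon genes, early and late inflammatory genes, dendritic cell maturation, both classes of MHC presentation, the unfolded protein response, heat shock, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, lysosome, ribosomal proteins, cell cycle, receptors and signalling proteins, reference genes and sex-linked genes. Markers of dendritic cells, plasmacytoid dendritic cells, macrophages, neutrophils, mast cells with basophils and eosinophils, T and NK cells, B cells, erythroid cells and fibroblasts with endothelial cells were listed as well. Lists with at least 3 tested members were tested with camera in limma, against all other genes, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The estimated correlation rests on 2 residual degrees of freedom, which leaves little power, so a list that fails with it is left undecided.

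Genes are named by a rule. It takes the gene targeted in a knockout. It takes, among genes past the threshold with a difference of at least 1, the 6 largest increases and the 6 largest decreases, leaving out predicted transcripts without a symbol and, with 2 cultures in both arms, genes whose arms overlap. It takes from each list the 5 members with the largest absolute difference. For shares of cells, a fixed set of 16 genes was used.

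The share of cells with a gene counts kept cells at a TPM of 10 or more. A cell was counted as having the antiviral programme when at least 50% of the antiviral list's members reached that TPM. Intervals are 95% exact (Clopper-Pearson) intervals from scipy 1.17.1, and a share of 0 is given with the limit that 3 cells would set. Intervals and limits cover counting error only, not the spread between cultures. Each population control was compared with the mean of the cells of each culture of its condition by Pearson's r across genes.

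The test was tried on simulated culture values. They were each gene's mean plus random spread, drawn independently for every gene and culture and scaled from the replicates. Known changes were added to genes with a mean above 1. For LPS 4 h against unstimulated cultures, 0.4% of genes were recovered at a difference of 1, 5.6% at 2, 69.6% at 4 and 90.8% at 6. For the Ifnar1 knockout at LPS 4 h, a lone culture, 0% were recovered at 1, 1.2% at 2, 50% at 4 and 79.2% at 6. For the second table's LPS 4 h against 2 h, 6.8% were recovered at 1 and 83.6% at 2. Between 3.8% and 5.8% of calls were false. No unchanged list of 100 was called, and 5 of 5 changed lists were. In the simulation genes were independent and all cultures varied alike, as the tests assume. These rates need not hold for correlated genes or for cultures that differ in their mix of cells.

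The comparisons, the filters, the lists, the rule for naming genes and most of the alternatives were chosen before the data were examined. Those alternatives were a pseudocount of 10, no filter on low genes, all cells, cells with at least 3000 genes, log2 of the mean TPM, quantile normalization, leaving out each replicate, a replicate block, a fit of the 4 replicated cultures only, a TPM of 1 for shares, 25% of the list's members for the programme, and all genes for the population controls. Chosen after seeing the data were a restriction to cells with Lyz2 at a TPM of 100 or more, a restriction to genes with a mean value of at least 1, and limma without the variance trend. Values were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.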

Results

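The series held 2412 single BMDCs, cells grown from bone marrow that sense microbes, and 13 population controls. Its design text names 1775 single cells, fewer than the 2 tables hold. The first table followed stimulation with LPS (bacterial endotoxin), PAM (a synthetic mimic of bacterial lipopeptides) and PIC (poly(I:C), a mimic of viral double-stranded RNA) over 1, 2, 4 and 6 h. It also held recombinant interferon beta (IFNB) for 2 h, LPS 4 h in 3 knockouts, and LPS 4 h with cells sealed singly in the chambers of a microfluidic chip. The second table held LPS at 2 and 4 h, an Ifnar1 knockout at 2 h, LPS with the secretion blocker GolgiPlug (brefeldin A) added at 0, 1 or 2 h, LPS at 0.1X dose, and unstimulated cells on the chip. Kept cells numbered 45 to 94 per culture in the first table and 37 to 71 per set in the second. Median genes per kept cell ran from 2755 to 4777.5 and from 2649 to 3434.5, and read depth is unknown. Zeros in the tables need care, since the reference gene Gapdh was listed at 0 in 1208 of the 1848 cells of the first table and in none of the 13 controls. Gapdh reached at most 105.84 TPM in a cell. It stood apart from the other reference genes counted, which were at 0 in 12 (Actb) to 119 (Rplp0) of those cells. Actb reached 142064.46 TPM, so the zeros of Gapdh do not show how often other transcripts were missed.

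What LPS did to wild-type cells was asked at 4 h, where both arms had 2 cultures. Antiviral genes were among the largest increases. Rsad2, which blocks viral budding, was at 9.47 against 0.45 (+9.02 ± 0.83, adjusted p = 0.018), and Ifit1, a sensor of viral RNA, was at 9.19 against 0.43 (+8.76 ± 0.71, adjusted p = 0.013). Ifit2 rose by +8.34 ± 0.61 and Cxcl10, a chemokine that draws T cells, by +8.95 ± 1.24 with an adjusted p of 0.0499. The cytokines Il6 (+8.49 ± 0.69) and Il12b (+8.42 ± 0.75, 9.66 against 1.25) and the costimulatory receptor Cd40 (+6.36 ± 0.69) rose too, each in both cultures. The neutrophil-activating cytokine Il1b was at 7.64 against 1.37, which did not pass (adjusted p = 0.15). All 47 tested antiviral genes were higher, with a median of +4.81, and 21 passed over all genes and 46 when adjusted over the list alone. Late inflammatory genes were also higher in all 29 members (median +1.83, 5 passing, 18 adjusted over the list alone). Early inflammatory genes had a median of +0.81 with 0 passing and 13 rising and 1 falling when adjusted over the list alone. Camera gave adjusted p = 3.0e-66, 1.8e-23 and 3.6e-06 for the antiviral, late and early lists, against adjusted p = 0.33 for each with an estimated correlation.

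In limma 45 genes rose and 0 fell at LPS 4 h, with 1429 genes at an unadjusted p under 0.05. Without either LPS 4 h culture or either unstimulated culture the count was 0, and a replicate block gave 586, 355 rising and 231 falling. Among genes with a mean of at least 1, 190 rose and 42 fell. A pseudocount of 10, log2 of the mean TPM and limma without the variance trend each gave 0. The share of cells with Lyz2 at a TPM of 100 or more was 94.3% and 59.8% in the LPS cultures and 71.6% and 55.7% in the unstimulated ones, and among those cells 104 genes rose and 3 fell.

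The order of the response was followed at 1, 2 and 6 h against unstimulated cells, each time in 1 culture. At 1 h the early list led, with a median of +3.30 (camera adjusted p = 4.2e-19, and adjusted p = 0.27 with an estimated correlation). Of its 38 members 0 passed over all genes and 27 rose when adjusted over the list alone. The chemokine Cxcl2 was at 8.82 against 1.48 (adjusted p = 0.11) and the cytokine Tnf at 7.97 against 0.92 (adjusted p = 0.18). Cell cycle genes were higher at 1 h by a median of +0.99 (adjusted p = 9.2e-11, and adjusted p = 0.84 with an estimated correlation), 10 of 26 rising when adjusted over the list alone. That culture had a median of 4777.5 genes per cell against 3988.5 and 3382, and Lyz2 at a TPM of 100 or more in 97.7% of cells against 71.6% and 55.7%. The antiviral list differed in sign between its median (-0.09) and its mean (+0.02) at 1 h, and camera placed it below the other genes with an adjusted p of 0.028, and adjusted p = 0.97 with an estimated correlation. The median turned to +0.36 without unstimulated culture 1, with 41 of 47 members higher, and was -0.54 without culture 2, with 9 higher. At 2 h the interferon gene Ifnb1 rose by +2.77 ± 0.20 (adjusted p = 0.019), from a listing of 0 in the unstimulated cultures. The T cell costimulator Tnfsf9 rose by +7.35 ± 0.54. For Ifnb1 the replicates behind that p-value lay near 0, at 0.0 and 0.0 unstimulated and 0.38 and 0.25 at LPS 4 h. The second table's LPS 2 h sets had 5.71 and 4.66, so the spread of Ifnb1 where expressed is not measured by that p-value. The antiviral list was higher by a median of +1.05 at 2 h (adjusted p = 4.5e-12, and adjusted p = 0.73 with an estimated correlation) and by +4.90 at 6 h (adjusted p = 1.1e-65, and adjusted p = 0.33 with an estimated correlation). Leaving out unstimulated culture 1 or 2 gave medians of +1.73 or +0.64 at 2 h and +5.96 or +4.25 at 6 h.

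At 6 h Rsad2 rose by +10.05 ± 1.02, Il12b by +9.51 ± 0.92 and Il6 by +9.28 ± 0.85. Late inflammatory genes had a median of +2.58 (adjusted p = 5.2e-27, and adjusted p = 0.33 with an estimated correlation), 3 passing and 15 adjusted over the list alone. MHC class II genes were lower by a median of -1.58 (adjusted p = 0.01, and adjusted p = 0.42 with an estimated correlation), with 0 passing over all genes and 1 falling when adjusted over the list alone. That call was lost without unstimulated culture 2 (adjusted p = 0.310), with all cells (0.0717) and in cells with high Lyz2 (0.0879). Of the members, H2-Aa was at 8.77 against 11.66 (adjusted p = 0.56). Limma called 2 genes at 1 h (Nr4a1 and Gm889), 2 at 2 h and 16 at 6 h, all rising, with 1368, 793 and 1091 at an unadjusted p under 0.05. Each count was 0 without any 1 of the replicated LPS 4 h or unstimulated cultures and without the variance trend, and with all cells the 1 h count was 156.

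**Figure D1:**
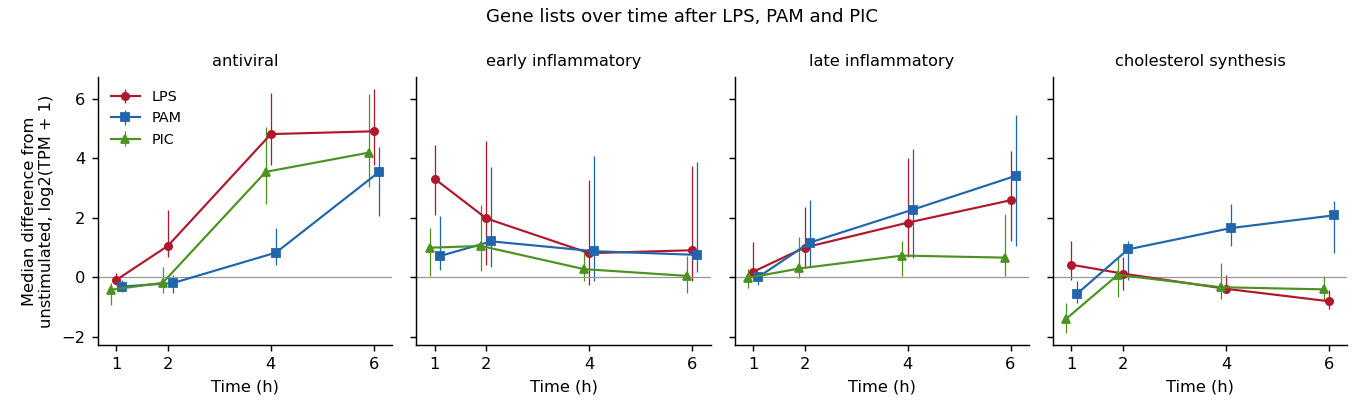
Median difference from unstimulated cultures (log2(TPM + 1), points, with bars over the quartiles of the list members) for 4 gene lists at 1, 2, 4 and 6 h of LPS, PAM and PIC. The antiviral list reached +4.81 at 4 h of LPS and +0.83 at 4 h of PAM. Leaving out unstimulated culture 1 or 2 gave +5.68 or +3.84 for LPS and +1.32 or +0.34 for PAM.

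Bacterial lipopeptide and viral RNA mimics were set against LPS at 4 h to ask which genes depend on the stimulus. With PAM the antiviral genes were lower than with LPS in all 47 members (median -3.72), and 43 fell when adjusted over the list alone. Cxcl10 was at 0.91 against 9.35 (adjusted p = 0.38), Rsad2 at 1.45 against 9.47 (adjusted p = 0.22) and Ifit2 at 1.16 against 8.86 (adjusted p = 0.12). Cholesterol synthesis genes were higher with PAM, by a median of +1.98, and 9 of 20 rose when adjusted over the list alone. Among them were the sterol enzymes Sc5d (7.0 against 3.41, adjusted p = 0.50) and Sqle (4.80 against 1.38, adjusted p = 0.39). Camera gave adjusted p = 2.6e-72 for the antiviral and 4.2e-14 for the cholesterol list, and adjusted p = 0.50 for both with an estimated correlation. With PIC no gene passed. Il12b was at 2.24 against 9.66 and Il6 at 1.78 against 8.65 (both adjusted p = 0.37), while the lipid A co-receptor Cd14 was at 3.57 against 7.97 (adjusted p = 1.0). Late inflammatory genes were lower with PIC (median -0.93, adjusted p = 1.0e-11, and adjusted p = 0.65 with an estimated correlation), 5 falling when adjusted over the list alone. Antiviral genes were lower by a median of -1.19 (adjusted p = 2.9e-10, and adjusted p = 0.65 with an estimated correlation), with 0 adjusted over the list alone. With log2 of the mean TPM that median was -0.28 and the call was lost (adjusted p = 0.0892). Heat shock genes were lower by -0.67 (adjusted p = 0.0089, and adjusted p = 0.65 with an estimated correlation). Limma called 0 genes for either stimulus, with 529 for PAM and 391 for PIC at an unadjusted p under 0.05. Each is a share below 0.05 of the 11537 genes tested, so neither shows an excess of low p-values. With no filter on low genes the counts were 197 (181 rising and 16 falling) and 349 (329 rising and 20 falling). That fit took in 27723 genes and had 0.68 prior degrees of freedom, against 4.84. In it LPS 4 h against unstimulated, with 2 cultures in each arm, gave 1 gene. These counts of lone cultures are therefore weak evidence of differences between the stimuli. The PIC 4 h culture had Lyz2 at a TPM of 100 or more in 59.4% of cells and the PAM 4 h culture in 85.7%.

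Against unstimulated cells the stimuli differed in timing, and those differences were not tested. After PAM the antiviral list stood at a median of -0.31 at 1 h (adjusted p = 0.0059, and adjusted p = 0.74 with an estimated correlation), -0.20 at 2 h, +0.83 at 4 h (adjusted p = 3.9e-08, and adjusted p = 0.87 with an estimated correlation) and +3.53 at 6 h (adjusted p = 1.2e-41, and adjusted p = 0.30 with an estimated correlation). After PIC it stood at -0.42, -0.19, +3.54 and +4.18, with adjusted p = 2.4e-73 at 4 h and 3.9e-46 at 6 h and adjusted p = 0.60 and 0.63 with an estimated correlation. At 6 h of PIC 23 antiviral genes rose over all genes, 16 without LPS 4 h culture 1 or 2, 18 without unstimulated culture 1, and 4 without unstimulated culture 2 or with log2 of the mean TPM. The early list was higher at 2 h of PAM (+1.2, adjusted p = 1.1e-16, and adjusted p = 0.31 with an estimated correlation) and of PIC (+1.05, adjusted p = 1.5e-14, and adjusted p = 0.36 with an estimated correlation). Late inflammatory genes were higher at 6 h of PAM by +3.40 (adjusted p = 5.2e-32, and adjusted p = 0.22 with an estimated correlation), with 6 rising over all genes and 18 adjusted over the list alone. Of those 6 calls 0 were left without LPS 4 h culture 1 or either unstimulated culture, and 2 without LPS 4 h culture 2. Cholesterol genes were higher then by +2.08 (adjusted p = 1.9e-12, and adjusted p = 0.29 with an estimated correlation), 8 of them when adjusted over the list alone. Camera placed the antiviral list above the other genes at 2 h of PAM and PIC, against the sign of its medians, and neither test passed (adjusted p = 0.73 and 0.64). The PAM medians at 1, 2, 4 and 6 h moved with the unstimulated culture left out. They were +0.07, +0.20, +1.32 and +4.16 without culture 1, and -0.77, -0.55, +0.34 and +2.69 without culture 2. Without unstimulated culture 2 the antiviral test at PIC 1 h passed, and without culture 1 that at PAM 1 h did not.

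IFNB for 2 h tested what interferon alone does. All 47 antiviral genes were higher than in unstimulated cells, by a median of +3.19, and 35 rose when adjusted over the list alone. Rsad2 was at 9.01 against 0.45 and Ifit1 at 8.14 against 0.43 (both adjusted p = 0.079), and Irf1, a transcription factor of the interferon response, was at 7.81 against 2.53 (adjusted p = 0.21). The chemokine Ccl5 was at 3.78 against 9.20 (adjusted p = 0.19). Camera gave adjusted p = 1.8e-36 for the antiviral list, and adjusted p = 0.60 with an estimated correlation. MHC class II (median -1.13, adjusted p = 0.00052) and cholesterol genes (-0.83, adjusted p = 8.9e-06) were lower as groups, each at adjusted p = 0.60 with an estimated correlation. The MHC class II call was lost without unstimulated culture 2 (adjusted p = 0.0550). Lyz2 was at a TPM of 100 or more in 90.4% of cells against 71.6% and 55.7%. Limma called 0 genes, with 881 at an unadjusted p under 0.05, and 43 among genes with a mean of at least 1.

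Loss of Ifnar1, a chain of the receptor for type I interferon, tested how far the LPS response runs through that receptor. Ifnar1 itself was at 1.96 in the knockout and 3.65 in the wild type at LPS 4 h (-1.70 ± 0.69, adjusted p = 0.48), and ran from 1.93 to 5.68 in the other cultures of the first table. The antiviral Ifit2 (-8.86 ± 0.75, from 8.86), the GTPase Ifi47 (-8.48 ± 0.74) and Ifit3 (-7.55 ± 0.66, from 7.55) fell, each at adjusted p = 0.039, and Ifit2 and Ifit3 were at 0.00 in the knockout. They were the only 3 genes that passed, with 1163 at an unadjusted p under 0.05 in limma. Usp18, a brake on interferon signalling, was at 0.06 against 9.11 (adjusted p = 0.068), Rsad2 at 0.64 against 9.47 and Il12b at 2.00 against 9.66 (both adjusted p = 0.060). The neutrophil chemokine Cxcl1 was at 7.90 against 3.98 (adjusted p = 0.15). The antiviral list had a median of -4.86, 45 of 47 falling when adjusted over the list alone (camera adjusted p = 1.2e-56, and adjusted p = 0.88 with an estimated correlation). MHC class I genes (median -1.72), among them the peptide transporter Tap1 at 1.38 against 5.55, and maturation genes (-1.59) were lower as groups, both at adjusted p = 7.2e-05 and adjusted p = 0.88 with an estimated correlation. In the knockout 90.3% of cells had Lyz2 at a TPM of 100 or more, against 94.3% and 59.8%. The count was 0 without any 1 of the replicated LPS 4 h or unstimulated cultures and without the variance trend. With all cells it was 74, and in cells with high Lyz2 it was 30.

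Loss of Stat1, the transcription factor downstream of that receptor, was tested the same way. Stat1 fell to 0.38 from 6.52 (-6.14 ± 0.95, adjusted p = 0.042), and every other culture of the first table had at least 0.99. Antiviral genes fell, among them Ifit2 (-8.27 ± 0.75), Oas1a (7.68 to 0.00) and Ifit3 (7.55 to 0.04). So did Ifi47 (-8.34 ± 0.74), which is outside the antiviral list. In that list 16 members fell over all genes (0 without LPS 4 h culture 1 or 2, 3 or 2 without unstimulated culture 1 or 2) and 42 when adjusted over the list alone, with a median of -4.51 (camera adjusted p = 1.8e-36, and adjusted p = 0.34 with an estimated correlation). The interleukin Il15, which sustains NK cells, fell from 7.17 to 0.96. Other genes rose. Retnla, a marker of alternatively activated macrophages, rose to 9.94 from a listing of 0 (adjusted p = 1.8e-05), Pf4 by +6.18 ± 0.84, the complement gene C1qb by +5.38 ± 0.79, Cxcl1 by +5.30 ± 0.78 and the protease inhibitor Serpinb2 by +4.92 ± 0.49. Rpl29 rose by +8.80 ± 0.44.

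Macrophage markers were higher in the Stat1 knockout as a group (median +0.86, adjusted p = 0.0054, and adjusted p = 0.48 with an estimated correlation), 3 of 16 passing. MHC class II genes were higher by +2.40 (adjusted p = 8.4e-05, and adjusted p = 0.34 with an estimated correlation), 0 passing over all genes and 1 adjusted over the list alone (adjusted p = 0.0518 with quantile normalization), and MHC class I genes were lower by -1.66 (adjusted p = 3.2e-05, and adjusted p = 0.59 with an estimated correlation), 5 adjusted over the list alone. The 3 tested mast cell, basophil and eosinophil markers had a median of +0.55 (adjusted p = 0.00036, and adjusted p = 0.34 with an estimated correlation), and Gata2, a factor of mast cells and progenitors, rose by +2.57 ± 0.12. The animals were of strain 129S6 and all wild-type cultures of C57BL/6, and 36.7% of knockout cells had the Y-linked Eif2s3y, seen in 0 cells of every other culture, which allows up to 3.19% to 8.11% by culture. Xist, expressed in females, was at 0.00 against 2.84. In limma 71 genes rose and 42 fell, 1190 reaching an unadjusted p under 0.05. Increases made up 62.8% of the calls, 75.9% with quantile normalization, and 25.8% among genes with a mean of at least 1, where 46 rose and 132 fell. Leaving out LPS 4 h culture 1 or 2 gave 16 genes, and leaving out unstimulated culture 1 or 2 gave 48 or 49. Log2 of the mean TPM gave 9 and limma without the variance trend 1, and Retnla and Eif2s3y were called against replicated cultures all listed at 0.

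The double knockout of the receptors for TNF tested feedback through that cytokine. Tnfrsf1a was at 1.93 against 2.34 (adjusted p = 0.85) and Tnfrsf1b at 4.11 against 6.59 (adjusted p = 0.67) at LPS 4 h. In the other cultures of the first table they ran from 1.52 to 3.75 and from 4.10 to 8.57. Transcript outside the deleted parts would not test a knockout, and the deleted parts are not stated. Il12b was at 4.99 against 9.66, the adaptor Samsn1 at 2.13 against 6.84, the cytokine Il27 at 6.23 against 2.67 and C1qb at 7.10 against 3.45 (all adjusted p = 0.67). Maturation genes were lower as a group (median -2.15, camera adjusted p = 0.00093, and adjusted p = 0.83 with an estimated correlation), 2 of them when adjusted over the list alone, and Lyz2 was at a TPM of 100 or more in 93% of knockout cells against 94.3% and 59.8%. Without LPS 4 h culture 2 the maturation median was -1.12 and the call was lost (adjusted p = 0.0558). Glycolysis and hypoxia genes were higher (+0.39, adjusted p = 5.6e-05, and adjusted p = 0.83 with an estimated correlation). The antiviral list had a median of -0.35 and a mean of -0.20, while camera placed it above the other genes (adjusted p = 0.046, and adjusted p = 0.83 with an estimated correlation). With all cells and with quantile normalization camera placed it below them. The call was lost without LPS 4 h culture 1 (median -0.46) and without unstimulated culture 1 or 2 (median -0.35 in each). It was kept without LPS 4 h culture 2, where the median turned to +0.09. Limma called 0 genes, with 794 at an unadjusted p under 0.05. The animals were of strain B6;129S, and the cells had a median of 2755 genes against 3919 and 3464.

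Cells stimulated with LPS on the chip, each in its own sealed chamber, were set against cells stimulated in open culture to ask what is lost without signals from neighbours. Antiviral genes were lower in all 47 members, by a median of -4.20, with 18 falling over all genes (0 without LPS 4 h culture 1 or 2, 6 or 8 without unstimulated culture 1 or 2) and 45 when adjusted over the list alone (camera adjusted p = 1.9e-32, and adjusted p = 0.66 with an estimated correlation). Ifit2 fell to 0.84 from 8.86 (-8.03 ± 0.75, adjusted p = 0.0050) and Ifit3 to 0.13 from 7.55. Ifi47, outside the list, fell to 1.49 from 8.68. Il12b fell by 8.77, to 0.90, and the T cell chemokine Ccl22 fell by 8.47. Early inflammatory genes were higher instead, with a median of +1.82 (adjusted p = 2.1e-05, and adjusted p = 0.66 with an estimated correlation), 6 rising over all genes and 14 adjusted over the list alone. The chemokines Cxcl2 (13.25 against 4.90, adjusted p = 0.024), Ccl2 (9.74 against 1.5, adjusted p = 0.0025) and Cxcl1 (10.51 against 3.98, adjusted p = 0.013) rose. Tnf was at 11.12 against 3.15 (adjusted p = 0.057).

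The heme-degrading enzyme Hmox1 (+7.37 ± 1.30), the ER chaperone Dnajb9 (+5.0 ± 0.56) and the ubiquitin ligase Syvn1 (+3.91 ± 0.47) rose on the chip as well. The unfolded protein list was higher by +1.40 (adjusted p = 0.00011), 4 of 30 rising over all genes and 8 adjusted over the list alone, the lysosome list by +1.88 (adjusted p = 0.00015), 0 rising over all genes and 8 adjusted over the list alone, and the oxidative phosphorylation list by +1.70 (adjusted p = 0.0012). Each had adjusted p = 0.66 with an estimated correlation. Maturation genes were lower by -3.12 (adjusted p = 4.2e-09, and adjusted p = 0.66 with an estimated correlation), 3 falling over all genes and 11 adjusted over the list alone. Of these, the homing receptor Ccr7 was at 0.00 against 6.10 (adjusted p = 0.16) and Cd40 fell by 6.70. The late list went both ways (median -0.29, adjusted p = 0.59), 5 rising and 4 falling. On the chip 100% of cells had Lyz2 at a TPM of 100 or more, against 94.3% and 59.8%. In limma 220 genes rose and 75 fell, with 2395 at an unadjusted p under 0.05. Among genes with a mean of at least 1, 325 rose and 284 fell, and with all cells 148 rose and 106 fell. Without LPS 4 h culture 1 or 2 the count was 36 or 25, and without unstimulated culture 1 or 2 it was 147 or 167. Log2 of the mean TPM and limma without the variance trend each gave 0.

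**Figure D2:**
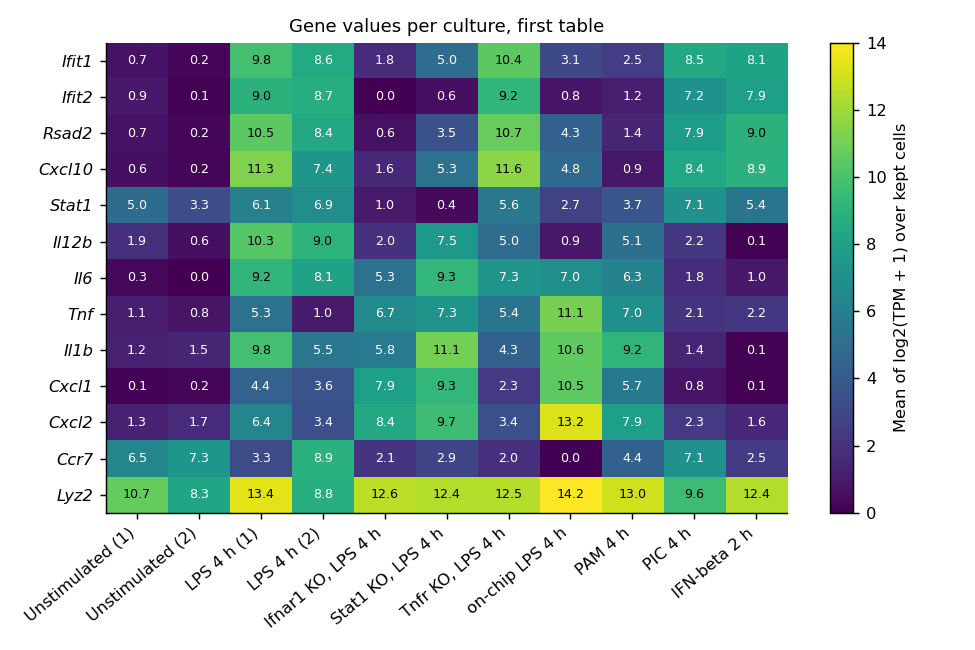
Culture means of log2(TPM + 1) over kept cells for 13 genes (vertical) in 11 cultures of the first table (horizontal), coloured from dark blue (0) to yellow (14). Ifit2 stood at 8.86 at LPS 4 h and at 0.84 on the chip, and Cxcl1 at 3.98 and 10.51.

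In the second table LPS 4 h was compared with LPS 2 h, where both arms had 2 technical sets. Antiviral genes rose between these times, with 42 of 47 passing and a median of +2.57 (camera adjusted p = 3.4e-43, and adjusted p = 0.10 with an estimated correlation). Usp18 rose from 2.88 to 10.46 (+7.58 ± 0.35, adjusted p = 8.4e-05) and Ifit3 from 0.91 to 7.37. Early inflammatory genes fell, 25 over all genes with 2 rising (median -1.20, adjusted p = 1.6e-05, and adjusted p = 0.51 with an estimated correlation). Ifnb1 fell from 5.19 to 0.35 (adjusted p = 0.00053), Il1b fell by 4.25, and Tnfsf9 (-5.36 ± 0.34) and Cd14 (-5.27 ± 0.26) fell too. Maturation genes rose in 14 members (median +1.72, adjusted p = 4.8e-14, and adjusted p = 0.32 with an estimated correlation), including the chemokine Ccl22 (+6.72 ± 0.36) and Ccr7 (+5.03 ± 0.39, from 1.62 to 6.65). Late genes rose in 12 members and fell in 2 (median +0.70, adjusted p = 1.2e-06, and adjusted p = 0.51 with an estimated correlation), Il12b rising from 3.68 to 9.47. Cholesterol genes fell in 10 members (median -0.99, adjusted p = 0.00024, and adjusted p = 0.32 with an estimated correlation), with Hmgcs1, an early enzyme of the pathway, going from 5.58 to 1.75.

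The ribonuclease Ear2 (9.74 to 1.24), the chemokine receptor Ccr2 (-6.70 ± 0.33) and Lyz2 (14.17 to 10.25) fell between 2 and 4 h in the second table too. In the first table Lyz2 was at 13.92 at LPS 2 h and at 13.44 and 8.83 in the LPS 4 h cultures. Of 16 macrophage markers 5 rose and 7 fell, the median (+0.22) and mean (-0.92) differed in sign, and the list did not pass (adjusted p = 0.99), while the share of cells with Lyz2 at a TPM of 100 or more was 97.9% and 91.3% at 2 h and 76.1% and 75% at 4 h. In limma 567 genes rose and 1575 fell, 2142 in all, with 3562 at an unadjusted p under 0.05. The median of all genes was -0.18, and with quantile normalization, which removes that shift, 48.7% of calls were increases against 26.5%. Leaving out either LPS 2 h set gave 0, LPS 4 h set 1 gave 1178 and set 2 gave 1010, and cells with at least 3000 genes gave 355.

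The Ifnar1 knockout at LPS 2 h was set against those 2 h sets. The column names of the knockout set carry another time code than the 2 h of its label, so a difference in time between the arms is not excluded. Ifnar1 was at 2.40 against 2.91 (-0.51 ± 0.37, adjusted p = 0.53) and ran from 2.0 to 4.6 in the other sets of the second table. Antiviral genes were lower by a median of -1.53 (camera adjusted p = 4.0e-22, and adjusted p = 0.20 with an estimated correlation), 14 falling over all genes and 31 adjusted over the list alone. Ifit1 fell from 7.22 to 1.99 (adjusted p = 0.0026), Cxcl10 from 9.81 to 5.04 and Rsad2 fell too (-4.83 ± 0.40). The cytokine Il6 (-3.24 ± 0.37) and Ccl5 (-3.94 ± 0.31) fell as well. Early genes were higher by a median of +0.51 (adjusted p = 0.00019, and adjusted p = 0.64 with an estimated correlation), 5 rising over all genes and 14 rising and 2 falling when adjusted over the list alone, with Egr2 at +3.25 ± 0.43 and Zfp36, which destabilises cytokine mRNAs, at +3.18 ± 0.38. Gpnmb, a glycoprotein of phagocytes, rose by +6.04 ± 0.40 and Ccr2 fell by 4.64. In limma 52 genes rose and 70 fell, with 1597 at an unadjusted p under 0.05. Quantile normalization made 52.8% of calls increases, against 42.6%. The count was 0 without either LPS 2 h set, 84 or 89 without LPS 4 h set 1 or 2, 32 without the variance trend, and 2 in cells with at least 3000 genes.

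GolgiPlug was added at 0 h to block secretion throughout the response. With 1 set, missing secreted signals cannot be told apart from other effects of the blocker, such as the rise of ER stress genes given below. Antiviral genes fell in 44 of 47 members, by a median of -4.25 (camera adjusted p = 1.1e-70, and adjusted p = 0.062 with an estimated correlation). Cxcl10 fell from 11.14 to 2.17 (adjusted p = 2.6e-05) and Usp18 fell too (-8.88 ± 0.43). Ifi47, outside the list, fell from 9.15 to 0.08. Late inflammatory genes fell in 11 members and rose in 1 (median -0.94, adjusted p = 1.0e-13, and adjusted p = 0.41 with an estimated correlation), including Il6 (-3.94 ± 0.37), and the early gene Il1b fell by 3.93. Genes of the unfolded protein and integrated stress responses rose in 12 of 29 members (median +0.95, adjusted p = 0.00033, and adjusted p = 0.41 with an estimated correlation). These included Ddit3, a factor of ER stress (6.27 against 0.85), Atf4 (+3.11 ± 0.53), Herpud1 (+3.02 ± 0.42) and the chaperone Hspa5 (9.98 against 7.66). Of the early list, Tnfsf9 (+6.30 ± 0.42), Ppp1r15a (+3.62 ± 0.48) and Cxcl1 (+3.58 ± 0.51) rose as well. Ribosomal protein genes rose in 6 members (median +0.62, adjusted p = 0.00055, and adjusted p = 0.41 with an estimated correlation), and as a list did not pass in cells with high Lyz2 (+0.31, adjusted p = 0.268). Lyz2 fell by 2.49, and 60.4% of cells had it at a TPM of 100 or more against 76.1% and 75%. Its direction turned with log2 of the mean TPM (+0.40).

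GolgiPlug at 1 h and at 2 h was set against the same LPS 4 h sets. Antiviral genes fell in 22 members at 1 h (median -1.21, adjusted p = 9.8e-13, and adjusted p = 0.35 with an estimated correlation), with Cxcl10 at 7.29 against 11.14. At 2 h 3 rose and 4 fell, the median (+0.02) and mean (-0.12) differed in sign, and the list did not pass (adjusted p = 0.088). Ddit3 (+5.05 ± 0.40) and Atf4 (+4.57 ± 0.53) rose at 1 h, where the unfolded protein list did not pass (adjusted p = 0.09), 8 members rising and 1 falling. Maturation genes fell in 14 members at 1 h (median -2.54, adjusted p = 1.2e-12, and adjusted p = 0.44 with an estimated correlation) and in 11 at 2 h (-1.79, adjusted p = 3.3e-11, and adjusted p = 0.59 with an estimated correlation). At 1 h and 2 h Ccl22 fell (-8.50 and -5.65), as did Ccr7 (-5.90 and -3.89) and Il12b (-8.08 and -7.28). With GolgiPlug at 0 h, the longest block, Ccr7 was at 6.07, against 6.24 and 7.07 in the LPS 4 h sets. Il12b was then at 8.82, against 8.93 and 10.01. The set with 0.1X LPS and no GolgiPlug had Il12b at 3.28. The falls of Ccr7 and Il12b thus did not grow with the length of the block, and all share the same LPS 4 h sets. The MHC class II chaperone Cd74 fell from 14.35 to 8.01 at 1 h, where 6 of the MHC class II genes fell and 1 rose (median -1.64, adjusted p = 0.00042, and adjusted p = 0.50 with an estimated correlation). Among single genes that rose at both times were Ear2 at +8.74 ± 0.37 and +7.92 ± 0.37, the lipoprotein Apoe at +7.18 ± 0.49 and +6.94 ± 0.49, and the receptor Tlr2 at +6.15 ± 0.43 and +4.62 ± 0.43. Macrophage markers rose in 7 and fell in 3 members at 1 h and rose in 7 and fell in 2 at 2 h, and as a list did not pass (medians +0.50 and +0.30, adjusted p = 0.081 and 0.25). Lyz2 rose by +4.65 ± 0.17 and by +3.71 ± 0.17, and 100% and 92.3% of cells had it at a TPM of 100 or more. Neutrophil markers were seen in a mean of 32.8% and 38.5% of cells per member, against 14.8% and 10.4% in the LPS 4 h sets.

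With GolgiPlug limma called 612 genes up and 318 down at 0 h, 1442 and 667 at 1 h, and 1038 and 374 at 2 h, with 2826, 3412 and 2830 at an unadjusted p under 0.05. All genes had median differences of +0.20, +0.12 and +0.13, and with quantile normalization 45.4%, 55.6% and 56.6% of calls were increases, against 65.8%, 68.4% and 73.5%. With log2 of the mean TPM they were 36.9%, 45.1% and 54.7%. Leaving out either LPS 2 h set gave 0 in each, and leaving out LPS 4 h set 1 or 2 gave 432 or 375, 1369 or 1227, and 858 or 766. Cells with at least 3000 genes gave 105, 301 and 315. Each GolgiPlug time had 1 set, so differences between these times were not tested.

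LPS at 0.1X dose for 4 h was set against the full dose. Antiviral genes rose in 13 members and fell in 1 (median +0.99, camera adjusted p = 0.0047, and adjusted p = 0.44 with an estimated correlation). The list lost the call among genes with a mean of at least 1 (adjusted p = 0.0923). Of its members, Eif2ak2, a kinase that senses viral RNA, was at +3.19 ± 0.36. Ifitm1, which is outside the list, was at -3.92 ± 0.41. Cholesterol genes rose in 10 members (median +1.06, adjusted p = 6.0e-05, and adjusted p = 0.43 with an estimated correlation), with Sc4mol at +3.60 ± 0.60 and Hmgcs1 at +2.94 ± 0.50. Maturation genes fell in 6 members (median -0.58, adjusted p = 5.7e-09, and adjusted p = 0.43 with an estimated correlation), and their median was -0.14 in cells with high Lyz2 and -0.20 in cells with at least 3000 genes. Among them were Ccl17 at -3.32 ± 0.31 and Ccr7 at -2.86 ± 0.47. Il12b fell from 9.47 to 3.28 and Tnf from 7.02 to 4.07, while Il1b rose from 8.01 to 10.93. Cd14 rose from 4.85 to 10.69, Ear2 from 1.24 to 9.55 and Lyz2 from 10.25 to 14.43, and 100% of cells had Lyz2 at a TPM of 100 or more. The same LPS 4 h sets served the comparisons with LPS 2 h and with GolgiPlug. Lyz2 was at 14.22 and 14.12 in the LPS 2 h sets and at 14.9 and 13.96 with GolgiPlug at 1 and 2 h. Its differences in these comparisons share the low LPS 4 h sets and are not independent of each other. Limma called 668 genes up and 107 down, with 2677 at an unadjusted p under 0.05, around a median of all genes of +0.21. Quantile normalization made 52.1% of calls increases, against 86.2%. The count was 0 without either LPS 2 h set, 250 without LPS 4 h set 1 and 167 without set 2, 91 in cells with high Lyz2, and 3 in cells with at least 3000 genes.

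The antiviral programme was also counted cell by cell. It was present in 4.5% of cells (95% interval 1.3 to 11.2) and in 0 of 61 cells in the unstimulated cultures, where 0 allows up to 4.92%. After LPS it was in 1.1% of cells at 1 h, 34.2% at 2 h (23.9 to 45.7), 100% (88 of 88; 95.9 to 100) and 94.3% (87.1 to 98.1) at 4 h, and 96.3% at 6 h. At 4 h PAM gave 25.4% (15.3 to 37.9) and PIC 75.4% (63.5 to 84.9), and at 6 h they gave 71.1% and 91.9%. IFNB gave 84.9% (74.6 to 92.2). At LPS 4 h the programme was in 0 of 62 Ifnar1 knockout cells, which allows up to 4.84%, in 2.5% of Stat1 knockout cells (0.3 to 8.8), in 100% of TNF receptor knockout cells (93.7 to 100), and in 16.7% of cells on the chip (10 of 60; 8.3 to 28.5). In the second table it was in 36.2% and 39.1% of cells at LPS 2 h and in 0 of 53 Ifnar1 knockout cells, which allows up to 5.66%. GolgiPlug added at 0, 1 and 2 h left it in 0 of 53 cells (up to 5.66%), in 73.3% (58.1 to 85.4) and in 96.2%, against 94.4% and 97.9% of cells without it. With 25% of the list's members the share was 55% on the chip and 50.6% in the Stat1 knockout, and 55.7% and 4.9% in the unstimulated cultures. It was then 28.4% and 83.5% at LPS 1 and 2 h, 54% and 97.8% at PAM 4 and 6 h, 11.3% and 22.6% in the Ifnar1 knockouts at 4 and 2 h, 83% and 84.1% at the second LPS 2 h sets and 20.8% with GolgiPlug at 0 h.

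**Figure D3:**
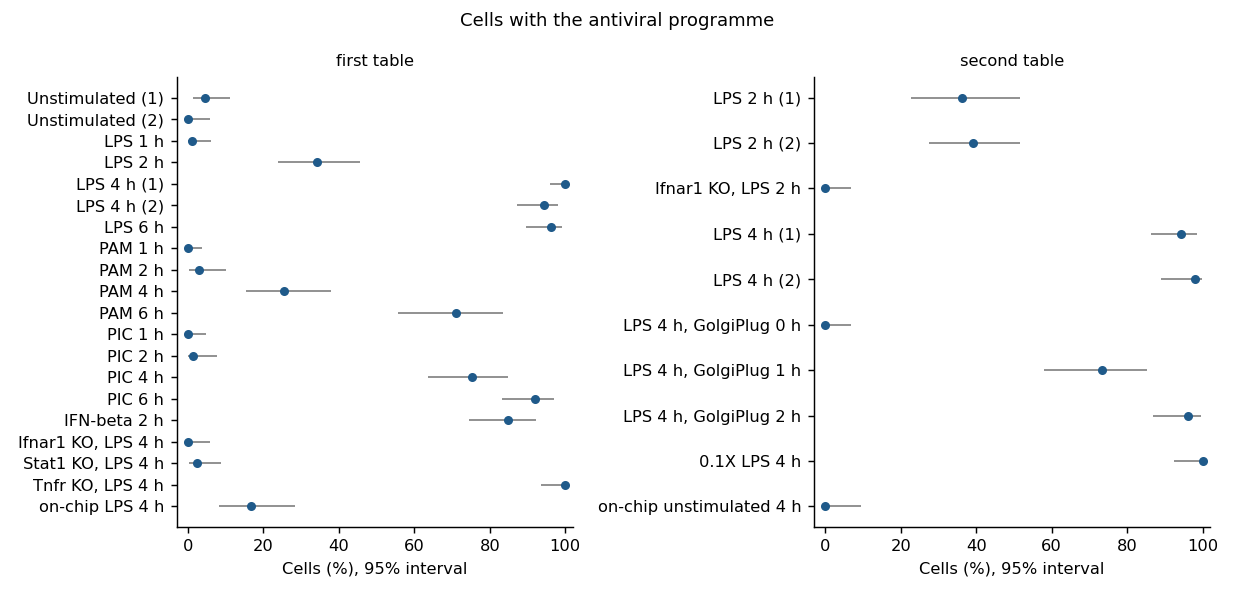
Percent of kept cells with the antiviral programme per culture or set (points), with 95% exact intervals (bars), in 1 panel for each table. LPS 4 h reached 100% and 94.3%, and the chip 16.7%.

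Among the LPS times of both tables the interferon gene Ifnb1 had its highest shares at 2 h. At a TPM of 10 or more it was in 8.0% of cells at LPS 1 h (3.3 to 15.7), 34.2% at 2 h (23.9 to 45.7), 5.7% and 3.4% at 4 h, and 4.9% at 6 h, and in 0 of 88 and 0 of 61 unstimulated cells, which allow 3.41% and 4.92%. In the second table Ifnb1 was in 61.7% and 47.8% of cells at LPS 2 h, in 39.6% of Ifnar1 knockout cells (26.5 to 54), and in 1.4% and 6.2% at 4 h. Its share at LPS 4 h was 22.8% in the Stat1 knockout (14.1 to 33.6) and 20% on the chip (10.8 to 32.3). Irf7, which amplifies interferon production, was in 70.5% and 88.5% of cells at LPS 4 h, in 16.7% on the chip, in 3.8% of Stat1 knockout cells and in 0 of 62 Ifnar1 knockout cells, which allows up to 4.84%. Tnf went the other way, from 62.5% and 10.3% at LPS 4 h to 100% on the chip (94 to 100), where Cxcl1 was in 88.3% against 45.5% and 37.9%. Il12b was in 15% of cells on the chip (7.1 to 26.6), against 93.2% and 82.8%. Differences in share between cultures were not tested, since each rests on 1 or 2 cultures. In the first table the type I interferon gene list was seen in a mean of 0.0% to 2.7% of cells per member.

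Cells with little Lyz2, the lysozyme of myeloid cells, made up very different shares of the cultures. Lyz2 was at a TPM of 100 or more in 55.7% to 100% of cells, and 0 to 3 cells per culture lay between a TPM of 50 and 200. In cultures with at least 5 cells below 100, Ccr7 was at a TPM of 10 or more in 90.5% to 100% of them. Markers of dendritic cells were seen in a mean of 28.9% to 46.1% of cells per member and those of macrophages in 21.1% to 51.5%. Markers of B cells reached at most 9.5%, of T and NK cells 9.4%, of mast cells, basophils and eosinophils 3.9%, and of erythroid cells and of fibroblasts and endothelial cells 0.9% each. For neutrophil markers the range was 1.9% to 12.3% in the first table, and for plasmacytoid dendritic cell markers 7.8% to 38.6% over both tables. Receptors and signalling proteins were seen in 26.8% to 41.1% of cells per member and sex-linked genes in 3.5% to 22.5%.

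**Figure D4:**
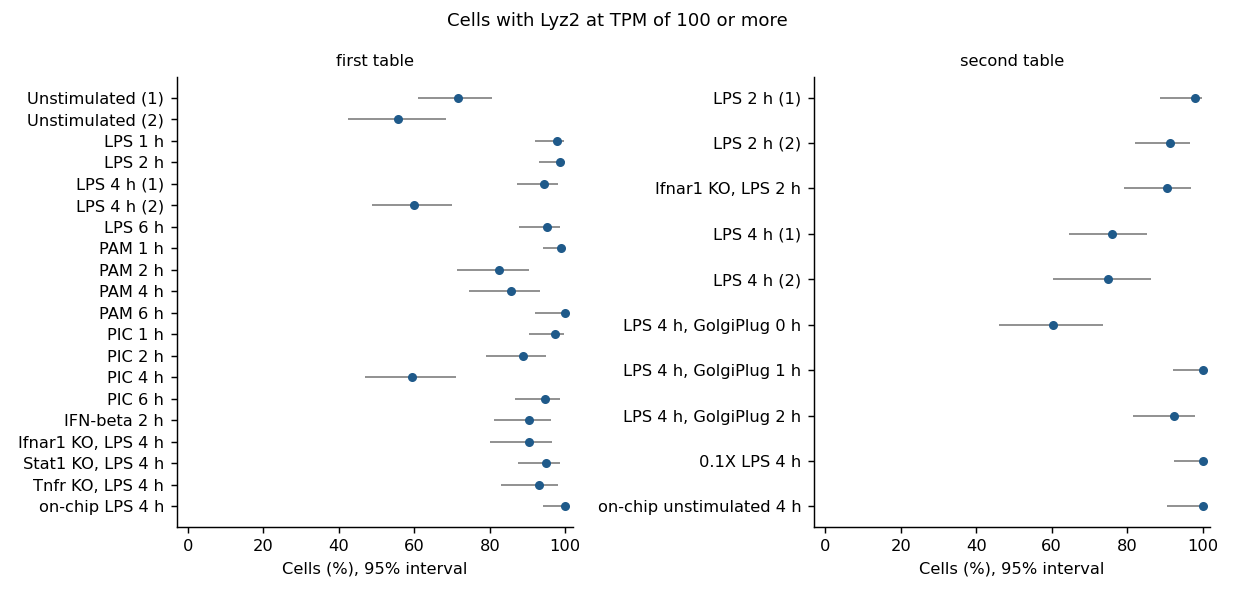
Percent of kept cells with Lyz2 at a TPM of 100 or more per culture or set (points), with 95% exact intervals (bars). Both unstimulated cultures (71.6% and 55.7%) lay below LPS 1 h (97.7%) and 2 h (98.7%).

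Population controls from tubes were compared with the mean of the cells of their condition's cultures across 11537 genes, which are not independent replicates. Pearson's r ran from 0.757 at PIC 6 h to 0.888 for the LPS 4 h control with culture 1. It was 0.829 for that control with culture 2, 0.813 and 0.778 for the unstimulated control with cultures 1 and 2, and 0.880, 0.882 and 0.862 at 1, 2 and 6 h of LPS.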

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

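The tests of this part were chosen only after the results were seen, apart from the lists and comparisons themselves. In 3 gene lists, LPS 1 h or 2 h and LPS 4 h lay on opposite sides of the unstimulated cultures, with every culture of one time higher than both unstimulated cultures and every culture of the other time lower. These differences were not tested, since 1 h and 2 h had 1 culture each. The scan covered the LPS series alone, where 4 h is the only time with 2 cultures. Dendritic cell maturation genes averaged 2.62 at 1 h and 3.67 at 2 h, against 4.3 and 4.62 in unstimulated cultures and 4.7 and 6.25 at 4 h, so 4 h minus 1 h was 2.85 and 4 h minus 2 h was 1.81. Cells with Lyz2 below a TPM of 100, mostly with Ccr7 in the unstimulated and LPS 4 h cultures, numbered 2 of 88 at 1 h and 1 of 79 at 2 h, against 25 of 88 and 27 of 61 unstimulated and 5 of 88 and 35 of 87 at 4 h, which does not order the cultures as the list does. Glycolysis and hypoxia genes averaged 4.32 at 1 h and 4.18 at 2 h, against 3.67 and 3.56 unstimulated and 3.51 and 3.48 at 4 h, which gave -0.82 and -0.68. Reference genes averaged 9.04 at 1 h, 8.64 and 8.55 unstimulated, and 8.17 and 8.24 at 4 h, which gave -0.84. Median genes per kept cell were 4777.5 at 1 h and 4141 at 2 h, 3988.5 and 3382 unstimulated, and 3919 and 3464 at 4 h.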

How the results depend on the processing

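Results were recomputed under the alternatives, of which the restriction to cells with high Lyz2, the restriction to genes with a mean of at least 1 and limma without the trend were chosen after seeing the data. Except where said, the cause of a change was not tested. TPM gives no read depth, so its effect could not be followed. Of the recomputed list results 786 kept their direction and side of the threshold, 91 lost the threshold, 3 gained it and 9 turned direction. Of the named genes' results 1948 kept both, 701 lost the threshold, 53 gained it and 4 turned. Of the counts 92 stayed within 1.5 times and 133 did not, and of the shares of cells 1283 stayed within their error and 277 did not. Both alternatives for the population controls moved.

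Counts of genes past the threshold moved as follows. With all cells they were 135 at LPS 4 h, 156 at 1 h, 4 at 2 h and 57 at 6 h, 5 for PAM, 74 for the Ifnar1 knockout at 4 h, 1 for the TNF receptor knockout and 10 for IFNB. In cells with high Lyz2 they were 107 at LPS 4 h, 1 at 1 h, 30 for Ifnar1 at 4 h, 4 for IFNB, 24 for Ifnar1 at 2 h and 91 for 0.1X LPS. In cells with at least 3000 genes they were 3 for the TNF receptor knockout, 355 for the second table's LPS 4 h against 2 h, 2 for Ifnar1 at 2 h, 105, 301 and 315 for GolgiPlug at 0, 1 and 2 h, and 3 for 0.1X LPS; fewer cells were averaged there. Among genes with a mean of at least 1, where fewer genes were tested, they were 232, 57, 37 and 174 at LPS 4, 1, 2 and 6 h, 49 for PAM, 2 for PIC, 156 for Ifnar1 at 4 h, 178 for Stat1 (46 rising and 132 falling), 7 for the TNF receptors, 609 on the chip, 43 for IFNB and 251 for Ifnar1 at 2 h.

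Log2 of the mean TPM gave 0 at each LPS time and on the chip, 9 for Stat1, 432 for the second table's LPS comparison, 18 for Ifnar1 at 2 h, 103, 490 and 203 for GolgiPlug at 0, 1 and 2 h, and 6 for 0.1X LPS. With no filter on low genes the counts were 1, 359, 356 and 617 at LPS 4, 1, 2 and 6 h, 197 for PAM, 349 for PIC, 199 for Ifnar1 at 4 h, 203 for Stat1, 109 for the TNF receptors, 204 for IFNB, 58 for Ifnar1 at 2 h and 477 for 0.1X LPS. For Ifnar1 at 4 h 176 of these rose and 23 fell, against 0 and 3 in the main fit. For Stat1 181 rose and 22 fell, against 71 and 42. In the first table the fit with no filter took in 27723 genes and had 0.68 prior degrees of freedom, against 4.84. Without the variance trend they were 0 at each LPS time, for Ifnar1 at 4 h and on the chip, 1 for Stat1 and 32 for Ifnar1 at 2 h. A pseudocount of 10 gave 0 at LPS 4 h and 6 h and for Ifnar1 at 4 h, 1 at LPS 1 h and at 2 h, 194 on the chip, 1313 for the second table's LPS comparison, 27 for Ifnar1 at 2 h, 517, 1263 and 738 for GolgiPlug at 0, 1 and 2 h, and 159 for 0.1X LPS. Quantile normalization gave 0 at LPS 1 h and 2 h and for Ifnar1 at 4 h, 9 at LPS 6 h and 438 for 0.1X LPS. A replicate block gave 586 at LPS 4 h, and 3038 in the second table's LPS comparison. Deviations of replicates with the same number correlated by 0.076 and 0.02 between conditions, so the numbers were not taken as pairs.

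Leaving out 1 replicate at a time, counts ran from 0 to 0 at each LPS time and for Ifnar1 at 4 h, from 16 to 49 for Stat1, from 25 to 167 on the chip, from 0 to 1178 for the second table's LPS comparison, from 0 to 89 for Ifnar1 at 2 h, from 0 to 432, from 0 to 1369 and from 0 to 858 for GolgiPlug at 0, 1 and 2 h, and from 0 to 250 for 0.1X LPS. With an arm left with 1 replicate, 1 residual degree of freedom remained.

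With an estimated correlation, which rested on 2 residual degrees of freedom and left little power, no list passed in any comparison. The antiviral list's adjusted p was then 0.328, 0.974, 0.733 and 0.330 at LPS 4, 1, 2 and 6 h, 0.505 and 0.649 for PAM and PIC against LPS, 0.876, 0.343 and 0.831 for the Ifnar1, Stat1 and TNF receptor knockouts at 4 h, 0.660 on the chip, 0.599 for IFNB, 0.102 for the second table's LPS comparison, 0.201 for Ifnar1 at 2 h, 0.0620 and 0.349 for GolgiPlug at 0 and 1 h, 0.436 for 0.1X LPS, 0.738, 0.874 and 0.304 at 1, 4 and 6 h of PAM, and 0.598 and 0.631 at 4 and 6 h of PIC. For the TNF receptor knockout it was 0.114 with all cells and 0.729 with quantile normalization, both with the list below the other genes in place of above them, 0.452 with high Lyz2, 0.197 with at least 3000 genes, 0.0502 with a mean of at least 1, 0.573 with log2 of the mean, 0.333 with no filter and 0.335 with a pseudocount of 10. At LPS 1 h it was 0.240 with log2 of the mean, 0.279 with no filter, 0.0761 with a pseudocount of 10 and 0.361 with quantile normalization. It was 0.0923 for 0.1X LPS with a mean of at least 1, 0.0892 for PIC against LPS with log2 of the mean, 0.0745 at PAM 1 h with a pseudocount of 10, and 0.016 and 0.0227 at PIC 1 h with log2 of the mean and with no filter. At PAM 2 h camera placed the list below the other genes, in place of above them, with a mean of at least 1 (0.777), no filter (0.924) and quantile normalization (0.978), and at PIC 2 h with no filter (0.724). Leaving out 1 replicate gave 0.000995 to 0.653 at LPS 1 h, 0.000125 to 0.350 at PAM 1 h, 0.139 to 0.816 at PAM 2 h, 0.0198 to 0.905 at PIC 1 h, 0.124 to 0.631 at PIC 2 h and 0.00225 to 0.449 for the TNF receptors.

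Among named genes Ifnb1 on the chip turned to -0.21 and Lyz2 with GolgiPlug at 0 h to +0.40 with log2 of the mean TPM, Tnfrsf1a in its knockout turned to +0.27 with quantile normalization, and Lyz2 at LPS 4 h ran from -0.65 to 3.96 when 1 replicate was left out. The median r of the 13 population controls was 0.831, against 0.868 with a pseudocount of 10 and 0.914 with all genes.

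The share of cells with the antiviral programme moved with its thresholds and with the cells kept. At a TPM of 1 it was 97.3% for IFNB, 8.0% and 54.4% at LPS 1 and 2 h, 98.9% in LPS 4 h culture 2, 33.3% on the chip, 41.3% and 88.9% at PAM 4 and 6 h, 8.9% for Stat1 and 13.6% in unstimulated culture 1, and among the second set of cells 59.6% and 55.1% at LPS 2 h, 88.9% and 100% for GolgiPlug at 1 and 2 h, and 100% in both LPS 4 h sets. With 25% of the members it was 98.6% for IFNB, 11.3% for Ifnar1 at 4 h, 28.4%, 83.5% and 100% at LPS 1, 2 and 6 h, 55% on the chip, 10.6%, 20.6%, 54% and 97.8% at PAM 1, 2, 4 and 6 h, 25.4%, 95.7% and 100% at PIC 2, 4 and 6 h, 50.6% for Stat1, 55.7% in unstimulated culture 1, 22.6% for Ifnar1 at 2 h, 83% and 84.1% at the second table's LPS 2 h, 20.8%, 97.8% and 100% for GolgiPlug at 0, 1 and 2 h, and 100% in both LPS 4 h sets. With all cells it was 67% for IFNB, 92.6% in LPS 4 h culture 1, 85.4% at LPS 6 h, 50% at PAM 6 h, 62.2% and 79.2% at PIC 4 and 6 h, and 70.8% for the TNF receptors. With at least 3000 genes it was 98.6% in LPS 4 h culture 2, 85.1% and 100% at PIC 4 and 6 h, 100% with GolgiPlug at 2 h and 100% in both LPS 4 h sets of the second table.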

Other observations

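Chosen only after the results were seen were all tests of explanations in this part. Unstimulated cells kept on the chip for 4 h entered no comparison, since no unstimulated set outside the chip was in the second table. Early inflammatory genes were seen in a mean of 41.9% of their cells per list member, late ones in 26.6%, genes of the unfolded protein response in 51.9%, MHC class II genes in 72.4% and macrophage markers in 51.5%. Tnf and Il1b were each in 37.8% of these cells at a TPM of 10 or more, and Lyz2 in 100%. Antiviral genes were seen in 8.3%. Ifit1, Cxcl10 and the antiviral programme were each in 0 of 37 cells, which allows up to 8.11%. Neutrophil markers were seen in 37.8% of these cells per member.

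At 1 h of PAM cell cycle genes were higher by a median of +1.17 (camera adjusted p = 8.8e-13, and adjusted p = 0.70 with an estimated correlation), with 1 rising over all genes and 14 adjusted over the list alone. The call was lost without either LPS 4 h culture or unstimulated culture 2, which left 0, and the PAM culture had a median of 4705 genes per cell against 3988.5 and 3382. At 1 h of PIC macrophage markers were higher by +2.31 (adjusted p = 9.7e-16, and adjusted p = 0.29 with an estimated correlation), 8 of them adjusted over the list alone, and Lyz2 was at a TPM of 100 or more in 97.3% of cells against 71.6% and 55.7% unstimulated. At 6 h of PIC ribosomal protein genes were lower by a median of -1.75 (adjusted p = 2.7e-05, and adjusted p = 0.74 with an estimated correlation). That culture had a median of 2848.5 genes per cell against 3988.5 and 3382, a median difference of all genes of -0.34, and the lowest r with its population control, 0.757.

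Antiviral genes were lower on the chip than in open culture at LPS 4 h. Fewer detected genes do not account for it, with a median of 4151 genes per cell on the chip against 3919 and 3464. A lower share of cells with little Lyz2 does not either, since the list's median in cells with high Lyz2 was -4.53, against -4.20 in all kept cells. The early list, at +1.82, cannot by itself tell whether cells missed the LPS, since unstimulated cells on the chip had early genes too. Tnf and Il1b were each in 37.8% of those cells, against 100% and 95% with LPS on the chip. Il6 and Ptgs2 were each in 0 of 37 unstimulated cells (up to 8.11%), against 85% and 93.3%. Cxcl1 was in 2.7% against 88.3%, and Cxcl10 and Rsad2 each in 0 of 37 against 60% and 56.7%. Of the fixed set of genes, only Ccr7 went the other way (2.7% against 0%), and Lyz2 was in 100% of both. For the genes covered, these shares argue against most cells on the chip having missed the LPS. The sets lie in different tables, and these differences were not tested. Missing signals from neighbours and handling on the chip may each play a part, and with 1 culture their shares were not tested.

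Maturation genes were lower than in the LPS 4 h sets with GolgiPlug at 1 h and 2 h and with 0.1X LPS. For GolgiPlug at 1 h the median was -2.06 in cells with high Lyz2 and -1.79 in cells with at least 3000 genes, against -2.54, so neither a lower share of cells with little Lyz2 nor the number of genes per cell accounts for the whole of it. The same holds at 2 h, with -1.7 and -1.1 against -1.79. For 0.1X LPS the medians were -0.14 and -0.2 against -0.58, so either may account for most of that difference. Effects of the treatments themselves remain open and untested, with 1 set each.

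Genes outside the antiviral list, such as Retnla, Pf4 and C1qb, were higher in the Stat1 knockout. The 71 such genes had a median difference of 2.32 in cells with high Lyz2 (quartiles 1.23 and 3.73) against 2.21 in all kept cells. They were picked for passing in these same cultures, whose kept cells mostly had high Lyz2. A kept difference was therefore likely from the start, and the share of cells with little Lyz2 was not put to an independent test. The sex-linked part fits male animals in the knockout culture, with Eif2s3y in 36.7% of its cells and Xist in 0 of 79, which allows up to 3.8%, and other genes could follow sex as well. Strain 129S6 and the lost gene cannot be told apart, since there were 0 wild-type cultures of that strain. An effect of Stat1 loss on these genes therefore stays open.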
